A study of Homo sapiens with 9 samples.

How the data were processed

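Polyadenylated RNA was sequenced from HEK293T cells, a human embryonic kidney line, that carried either a control short hairpin RNA (shNC) or 1 of 2 hairpins against SNU13 (sh15.5K-1 and sh15.5K-2). Per the labels, cells grew with 3 µM doxycycline and 1 µg/mL puromycin, and each of the 3 groups had 3 libraries from independent experiments, made with a strand-specific kit after poly(A) selection. One label names a colon cancer line while the source field and the design text name HEK293T. The name HEK293T is used here.

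The data analysed were 1 table of introns. Per the submitters' processing notes, the genome build was hg38, and cutadapt 2.0 and STAR 2.7.1a were used. The program that computed inclusion levels and their tests, and its settings, are not given in the sources used here. An inclusion level, between 0 and 1, is read here as the fraction of transcripts that keep the intron. Per the file headers, the authors deposited such a level for each intron, with 3 values per group. They also deposited a p-value, an adjusted p-value and a level difference for each hairpin against shNC. The deposited adjusted p-value equalled the Benjamini-Hochberg adjustment of the deposited p-value to within 1.9e-07, and the deposited difference equalled the difference of group means to within 0.00033, knockdown minus control. How reads were scaled by length is not stated. The table holds no read counts, so the depth behind each level is unknown, no interval for a single level is given, and no minimum coverage was applied. It holds no gene expression level either.

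The 3 values of a group carry no replicate number and were treated as unordered libraries of that group. Whether values at 1 position come from 1 library was checked by the share of introns at 0 per chromosome. The first listed value had the highest share in 23 of 23 chromosomes in shNC and in 21 in sh15.5K-2, but in sh15.5K-1 the first had it in 12 and the third in 10. The second had the lowest share in 22 chromosomes in shNC, 18 in sh15.5K-1 and 13 in sh15.5K-2, where the third had it in 10. In each group at least 1 position thus kept its place in most chromosomes, while the others were less clear in the hairpins. No pair of values within a group was a copy, since at most 7.46% of introns above 0 were identical to 3 decimals. All 9 libraries were kept, and the number of unmapped value columns was 0.

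The table lists 112869 introns of 11917 genes, of which 99372 have levels in all 3 groups. Start positions were found to count from 0 and are given here from 1. Against the GENCODE release 29 annotation of the same build, 99.82% of left and 99.8% of right intron edges met an annotated exon, and 11866 of 11917 gene identifiers were found. The annotation also gave exons inside introns, snoRNA genes inside introns on the same strand, and transcript types. An intron counts as holding an annotated exon when an exon of any gene, on either strand, overlaps it by at least 1 base. Exons that span the whole intron, exons on the other strand and snoRNA genes thus count too. No genome sequence was used, so U12-type introns could not be found by sequence and were replaced by a list of genes, and GC content was not analysed here.

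Levels were bounded to 0.01 and 0.99, turned into log odds and fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group over all 9 libraries and a prior variance that follows the mean level. Of the introns in all groups, 18906 were constant after bounding and 80466 were tested. A rise that stays under a level of 0.01, or a fall from such a level, cannot be seen on this scale. An intron is called higher or lower when its limma p-value, adjusted by the Benjamini-Hochberg method over all tested introns, is under 0.05. A log odds change is the natural logarithm of an odds ratio, and no minimum size was set. The contrasts were both hairpins together against shNC, each hairpin against shNC, and sh15.5K-1 against sh15.5K-2. On simulated data for the first contrast, 53% of 66 introns with a log odds change of 2 and 22.7% of 66 with a change of 1 were called, and none of 67 with a change of 0.5. Of 54 calls there, 4 were false. Only these few of 74189 simulated introns were changed, so the adjustment was stricter than in the real comparison, where 32.6% were called higher and 3.17% lower, and these shares are not its detection rate.

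Values per library were compared by exact two-sided permutation tests. Shares were compared by Fisher's exact test, two-sided, and medians by permutation tests with 100000 resamples. Of 589 symbols on 20 gene lists, 536 were in the table, 6 of them under another symbol. The lists were tested by the share of genes with a called intron, by limma's camera on gene means with a preset correlation of 0.01, and against 10000 random sets. Python 3.11.15, scipy 1.17.1, pandas 2.3.3 and statsmodels 0.14.6 were used.

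The groups, contrasts, bounds, threshold, gene lists, most alternatives and the rule for naming introns were fixed before the data were examined. That rule took the 10 largest rises and falls of level among called introns (1 per gene), SNU13, up to 4 members per list by adjusted p-value, and the 3 largest changes each way for snoRNA introns, the U12 gene list and the other contrasts. Alternatives chosen after seeing the data were 1 prior variance for all introns, introns without annotated exons, an arcsine scale, a minimum mean level, the authors' adjusted p-value, and the sets and bins matched on intron number or shNC level. Left out of all tests were introns listed for 1 hairpin only, 6203 for sh15.5K-1 and 7294 for sh15.5K-2, because a level was missing in another group. Some introns that the naming rule selected are not reported here.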

Results

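The data are intron inclusion levels from 9 poly(A) RNA libraries of HEK293T cells, 3 with a control hairpin and 3 with each of 2 hairpins against SNU13. The SNU13 protein binds the U4 and U4atac snRNAs of the spliceosome and the box C/D snoRNAs that guide rRNA methylation. The series compares knockdown with control cells for intron retention. An inclusion level of 0.1 is read here as an estimate that 10% of the transcripts across that interval keep the intron. Depth is unknown, and the number of libraries limits the precision.

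SNU13 itself was examined first. All 3 tested introns of SNU13 (ENSG00000100138, chromosome 22, hg38, minus strand) were retained more in both knockdowns, and each had all 6 knockdown libraries above the highest shNC library. The intron at 41675196 to 41680243 had a level of 0.00433 ± 0.00058 (SD, n = 3) in shNC, 0.135 ± 0.015 in sh15.5K-1 and 0.11 ± 0.0075 in sh15.5K-2. The intron at 41680365 to 41682355 went from 0.0387 ± 0.013 to 0.527 ± 0.22 and 0.458 ± 0.15, and the overlapping intron at 41680365 to 41688793 from 0.00133 ± 0.0012 to 0.122 ± 0.073 and 0.099 ± 0.016. The limma adjusted p-values for both hairpins together were 1.05e-05, 0.000389 and 0.000389. Each of these intervals holds an annotated exon, so a level there can count reads of another exon or isoform. The table has no expression level for SNU13, so the depth of the knockdown itself was not measured.

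Introns of most genes in the table were retained more when SNU13 was knocked down. In shNC libraries 23.0% ± 0.067 (SD, n = 3) of tested introns had a level of at least 0.1, against 32.98% ± 0.37 in sh15.5K-1 and 30.06% ± 0.2 in sh15.5K-2. The mean level was 0.1577 ± 0.00042, 0.1966 ± 0.0016 and 0.1868 ± 0.00059. With both hairpins together, 26214 introns in 7992 genes were called higher and 2552 introns in 1933 genes lower, of 80466 introns in 11152 genes, so that 91.1% of calls were rises. The median change of level was 0.0125, and 82.2% of introns had a change above 0. A level near 0 leaves little room to fall, and the lower bound hides falls under 0.01. Of 35068 introns with a shNC level of at most 0.01, 25.6% were called higher and 0 lower, which raises the share of rises. Of 3413 with a shNC level above 0.2 and up to 0.5, 45.7% rose and 12.2% fell. Of 8666 above 0.8, 9.54% rose and 10.7% fell.

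**Figure D1:**
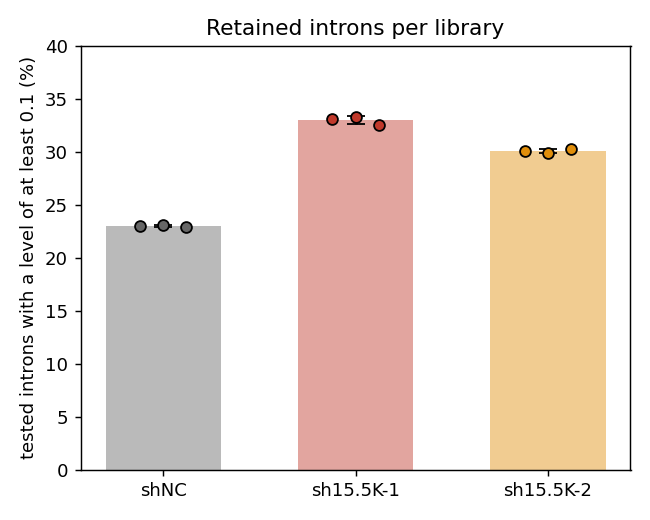
Share of the 80466 tested introns with an inclusion level of at least 0.1 (vertical axis, percent) in each group. Bars are means, error bars 1 SD over 3 libraries, and points single libraries: the shNC libraries lie between 22.94 and 23.07, the sh15.5K-1 libraries between 32.57 and 33.29, and the sh15.5K-2 libraries between 29.86 and 30.26.

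In the share of introns at or above 0.1, all 6 knockdown libraries lay above all 3 shNC libraries (exact permutation test, p = 0.0238, two-sided). That is the smallest p this test can give, and it treats the libraries of both hairpins as exchangeable. Counts of calls rest on limma with Benjamini-Hochberg adjustment. When a change of level of at least 0.1 was also required, 8477 introns were higher and 1248 lower.

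Large rises were seen in introns with shNC levels between 0.0317 and 0.183. An intron of MROH1 (chromosome 8, 144254979 to 144255508) went from 0.0613 ± 0.038 to 0.94 ± 0.055 in sh15.5K-1 and 0.959 ± 0.045 in sh15.5K-2. A 96 bp intron of RRAS, which encodes a Ras-family GTPase (chromosome 19, 49636728 to 49636823), went from 0.0317 ± 0.02 to 0.704 ± 0.064 and 0.78 ± 0.047. An intron of FANCA, a Fanconi anaemia DNA repair gene (chromosome 16, 89770025 to 89770165), went from 0.0627 ± 0.014 to 0.791 ± 0.057 and 0.724 ± 0.13. SLX4, a DNA repair scaffold, had an intron that rose from 0.183 ± 0.054 to 0.843 ± 0.026 and 0.869 ± 0.039. BTBD2, ABHD11, CES3, NUDT17 and PRPF40B, the last a homologue of a U1-associated splicing factor, also had introns among the 10 largest rises. The intervals of BTBD2, ABHD11, SLX4 and PRPF40B hold an annotated exon. The limma adjusted p-values of these named introns lay between 1.93e-05 and 0.000198, and in each all 6 knockdown libraries lay above the highest shNC library.

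The 10 largest falls were in intervals with shNC levels between 0.713 and 1.0. In CD46, a complement regulator, the interval at 207767196 to 207783291 on chromosome 1 had a level of 1.0 in all shNC libraries, 0.251 ± 0.067 in sh15.5K-1 and 0.208 ± 0.033 in sh15.5K-2. CDK4, the G1 cyclin-dependent kinase, fell from 0.981 ± 0.032 to 0.321 ± 0.03 and 0.266 ± 0.025 (chromosome 12, 57749505 to 57752174). BAG6 fell from 0.848 ± 0.065 to 0.142 ± 0.008 and 0.151 ± 0.024, and LARP1, which binds mRNAs of the translation machinery, from 0.714 ± 0.088 to 0.104 ± 0.02 and 0.079 ± 0.018. RAB18, RAB1B, TMEM161A, ACAD11, CHD1L and BCL2L12 had the other falls. Each of these 10 intervals holds an annotated exon. A level there can count reads of another exon or isoform, so a fall need not be a fall of an unspliced intron. Their limma adjusted p-values lay between 3.69e-06 and 0.00199.

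**Figure D2:**
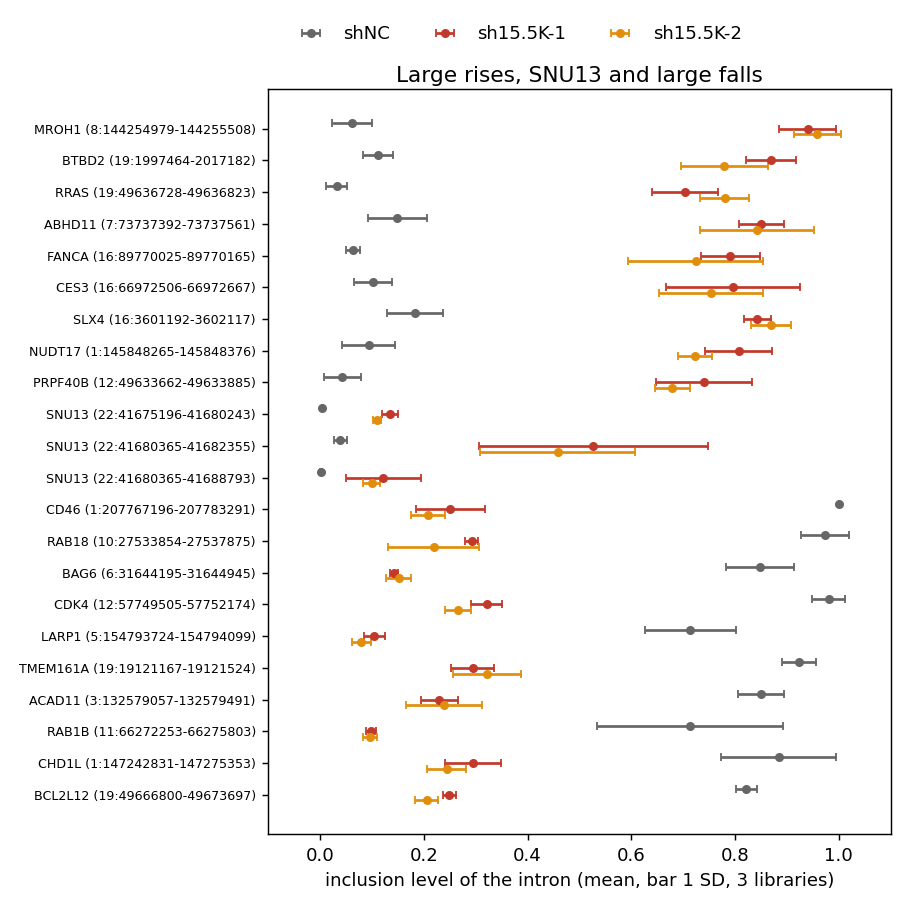
Inclusion level (horizontal axis, fraction from 0 to 1) of named introns among the 10 largest rises, the 3 introns of SNU13 and the 10 introns with the largest fall, with chromosome, start and end. Points are group means and bars 1 SD of 3 libraries for shNC (grey), sh15.5K-1 (red) and sh15.5K-2 (orange); the CD46 interval goes from 1.0 to 0.251 and 0.208.

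Each hairpin was also set against shNC on its own. With sh15.5K-1, 26598 introns were higher and 2185 lower. With sh15.5K-2, 19011 were higher and 1988 lower. MROH1 had the largest rise and CD46 the largest fall in both. Among the 3 largest rises were also BTBD2 and FANCA for sh15.5K-1, and RRAS for sh15.5K-2. Falls were led further by BAG6 and RAB18, and by RAB18 and CDK4. In both, 17317 introns were higher and 1492 lower, against 6284 and 54 if the lists were independent, and 3 were called in opposite directions.

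Both hairpins share the shNC libraries, which raises such overlaps. Across introns the log odds changes of the hairpins had r = 0.87, against 0.499 for simulated unchanged groups, and a covariance of 0.5501 against 0.0512. Simulated unchanged groups gave a mean of 0 shared calls. With no intron changed, hardly any call can arise there, so this does not measure how far shared controls raise the overlap. Introns are not independent replicates, 3 control libraries cannot give each hairpin at least 2 of its own, and part of the excess may come from the shared controls. In the authors' deposited table, 33549 of 105575 introns had an adjusted p-value under 0.05 for sh15.5K-1 (30600 higher, 2949 lower) and 28059 of 106666 for sh15.5K-2 (24945 higher, 3114 lower). For 3 libraries against 3, the exact permutation p of library means cannot go below 0.1, and it was 0.1 for each hairpin.

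Few introns were called between the hairpins, 154 higher and 25 lower in sh15.5K-1. At an unadjusted limma p under 0.05 there were 11029 introns (13.7%), and 66.6% of introns had a higher level in sh15.5K-1, so a low count of calls does not show that few introns differed. An intron of SLC2A6, a sugar transporter gene, had a level of 0.323 ± 0.079 with sh15.5K-1 but 0.021 ± 0.0053 with sh15.5K-2 and 0.028 ± 0.029 in shNC. Introns of SSH3, a cofilin phosphatase gene, and LMF2 had 0.497 ± 0.032 against 0.2 ± 0.044 and 0.437 ± 0.013 against 0.159 ± 0.037. The interval in ATP7B, the Wilson disease copper transporter gene, had 0.671 ± 0.073 against 0.956 ± 0.0065. RAB5IF had 0.359 ± 0.054 against 0.654 ± 0.039, and NSMAF 0.096 ± 0.027 against 0.38 ± 0.11.

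The limma adjusted p-values of these 6 introns lay between 0.0195 and 0.0479. The counts are not stable: leaving out any 1 library gave between 0 and 747 higher and between 0 and 56 lower, and 0 under several other settings. The median level change between the hairpins was 0.0047.

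Short introns rose most often. Of introns of 26 to 311 bp, the shortest 20%, 47.3% were called higher and 2.09% lower, and of those of 4389 to 593993 bp, the longest 20%, 19.7% and 4.03%. Across introns, Spearman's rho between length and log odds change was -0.208, and within genes with at least 5 tested introns the median rho was -0.159, below 0 in 65.3% of 6568 genes. Last introns were called higher more often (32.8%) than first introns (25.1%), with 30.2% for internal ones and 24.7% for the only intron of a transcript. The share was highest, at 38.9%, in the 25921 introns whose position differs between transcripts. The CDCA5 intron at 65083724 to 65083932 on chromosome 11, 209 bp long in the gene of the cohesion factor sororin, went from 0.046 ± 0.011 to 0.4 ± 0.0052 and 0.431 ± 0.015.

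Introns are not independent replicates, so no p is given for rho. Length and control level are related to detection: within bins of the shNC level rho was between -0.28 and -0.085, weakest for introns above 0.8. Within such bins the odds ratio of a rise was 0.816 (95% interval 0.769 to 0.865) for first and 1.14 (1.08 to 1.21) for last against internal introns, by Mantel-Haenszel. These intervals treat introns of 1 gene as independent. The comparison of positions was not matched on length, so position and length cannot be told apart there. GC content was not analysed here.

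**Figure D3:**
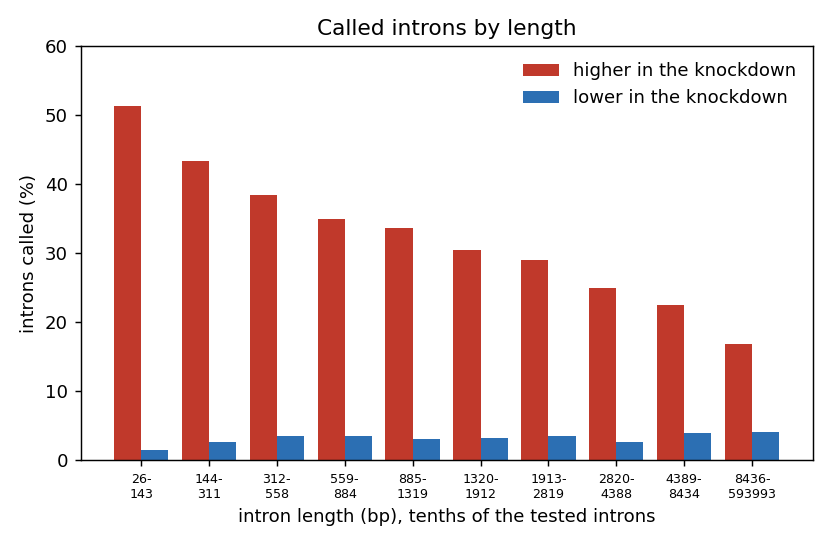
Share of introns called higher (red) and lower (blue) in the knockdown (vertical axis, percent) in 10 equal groups of intron length (horizontal axis, bp). Rises go from 51.3 in the shortest group to 16.9 in the longest, and falls from 1.54 to 4.11.

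Introns with and without an annotated exon inside rose about as often but fell at different rates. Of 36658 introns without one, 31.3% were higher and 0.887% lower. Of 43808 with one, 33.6% were higher and 5.08% lower. Within bins of the shNC level the odds ratio of a fall, with against without an exon inside, was 1.37 (95% interval 1.2 to 1.56). That interval treats introns of 1 gene as independent. Any overlap counts here, also by an exon that spans the interval or lies on the other strand. The split thus does not show how many levels held reads of another exon.

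Because the SNU13 protein also binds the U4atac snRNA of the minor spliceosome, genes known to carry a U12-type intron were compared with other genes. The 695 introns of 67 such genes were called higher in 31.5% and lower in 3.02%, against 32.6% and 3.17% of introns in other genes. The largest rises were in CCDC84, whose product belongs to the minor spliceosome, at 0.21 ± 0.049, 0.79 ± 0.029 and 0.675 ± 0.066, then TMEM161B and HTT, the huntingtin gene. The largest falls were in EXOSC2, EXOSC1 and BRAF, the kinase gene, the last at 0.991 ± 0.016, 0.836 ± 0.013 and 0.929 ± 0.061. On its own, sh15.5K-1 gave a call for BRAF (limma adjusted p = 0.0108) and sh15.5K-2 did not (0.178). All of these falling intervals hold an annotated exon, as do those of CCDC84 and TMEM161B. A fall there need not be a fall of an unspliced intron.

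The share called was not separated by Fisher's exact test (odds ratio 0.948, p = 0.525), but was lower with wider bounds on the level (0.854, p = 0.0257) and on an arcsine scale (0.838, p = 0.0118). Counted by gene the list went the other way, with 57 of 67 genes called (odds ratio 1.93, Fisher's exact test, adjusted p = 0.174), and passed in the same settings, with 65 genes (0.00727) and 63 genes (0.0407). The median log odds change differed from that of other genes by -0.09 (permutation test within length bins, p = 0.0084), a test that treats introns of 1 gene as independent. By camera on gene means the list went up relative to other genes and did not pass (limma adjusted p = 0.728 at the preset and 0.748 at an estimated correlation). Its median gene log odds change was nevertheless lower, at 0.351 against 0.435 over all genes, so the direction is not settled. Adjusted over the list alone, 217 introns rose and 21 fell, against 219 and 21 over all introns. All introns of these genes were counted, most of them not U12-type, so the comparison does not isolate U12-type introns, and the odds ratio was 1.22 among introns with a mean level of at least 0.05.

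Introns that hold a snoRNA were compared with other introns of the same 151 host genes. Of 164 introns with a box C/D snoRNA, 32.3% rose and 12.2% fell. Of 126 with a box H/ACA snoRNA, which the SNU13 protein does not bind, 35.7% rose and 6.35% fell. Of 1142 with none, 36.4% rose and 4.99% fell. The SNORD43 intron of RPL3, a ribosomal protein gene, rose from 0.474 ± 0.11 to 0.907 ± 0.052 and 0.857 ± 0.054. The SNORD10 intron of EIF4A1, a translation initiation helicase gene, fell from 0.94 ± 0.053 to 0.471 ± 0.034 and 0.622 ± 0.041.

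Among 12 tests, the share of falls in box C/D against no snoRNA had an odds ratio of 2.64 by Fisher's exact test (p = 0.00102, Benjamini-Hochberg 0.0122), and no other test passed. These tests treat introns of 1 gene as independent. Box C/D introns had higher shNC levels (median 0.208 against 0.015). Within bins of that level the odds ratio was 1.41, with a 95% interval of 0.798 to 2.49, and box C/D and box H/ACA introns were not separated by Fisher's exact test (odds ratio 2.05, p = 0.111). A snoRNA gene is itself an annotated exon, so every intron with a snoRNA counts as holding one, while other introns need not. The comparison with introns without a snoRNA was not matched on this, so the 2 features cannot be told apart there.

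Genes of the spliceosome and of snoRNPs carried introns that rose and introns that fell. Of 24 measured genes of the tri-snRNP, 23 had a called intron, among them CD2BP2 (0.00733 ± 0.0015 to 0.149 ± 0.0076 and 0.135 ± 0.024), PRPF31 and PRPF6. Of 13 box C/D snoRNP genes 9 had one, among them NOP56, whose product is a core protein (0.137 ± 0.018 to 0.495 ± 0.038 and 0.481 ± 0.009). Of 7 box H/ACA genes 5 had one, and in NHP2 and DKC1, core protein genes, the intervals fell, NHP2 from 0.334 ± 0.045 to 0.0753 ± 0.01 and 0.076 ± 0.015. Of 14 minor spliceosome genes 11 had one, among them SCNM1 and PPIL2. The named intervals of CD2BP2, PRPF31, NOP56, NHP2 and DKC1 hold an annotated exon, so a fall there need not be a fall of an unspliced intron. Introns that rose and fell numbered 55 and 9 of 156 for the tri-snRNP, 34 and 6 of 99 for box C/D, 12 and 4 of 43 for box H/ACA and 36 and 5 of 99 for the minor spliceosome. Adjusted over the list alone they numbered 55 and 9, 34 and 6, 12 and 4, and 37 and 5. Over all genes 74.8% had a called intron, and none of these 4 lists differed from that by Fisher's exact test with Benjamini-Hochberg adjustment over 20 lists (adjusted p between 0.0871 and 1.0). The tri-snRNP list, at 0.0871, passed Fisher's exact test on an arcsine scale (adjusted p = 0.0363) and without listed value 2 or 3 of sh15.5K-1 (0.024 and 0.0289) or value 3 of shNC (0.0411), but not with wider bounds (0.174), so its call depends on the setting.

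Genes of splicing regulators stood out for falls. In 12 SR protein genes 34 introns rose and 28 fell of 118, a share of falls of 23.7%. An interval of SRSF9 fell from 0.951 ± 0.015 to 0.713 ± 0.022 and 0.796 ± 0.022, while one of SRSF10 rose from 0.0497 ± 0.0091 to 0.358 ± 0.011 and 0.351 ± 0.017. In 21 hnRNP genes 72 introns rose and 29 fell of 207: HNRNPU rose from 0.299 ± 0.026 to 0.779 ± 0.031 and 0.703 ± 0.026, and HNRNPD fell from 0.784 ± 0.0061 to 0.437 ± 0.012 and 0.543 ± 0.012. In 16 genes of CLK kinases and other genes with regulated retained introns, 97 rose and 31 fell of 228, with a LUC7L3 interval falling from 0.534 ± 0.017 to 0.174 ± 0.0045 and 0.157 ± 0.0061. For SR proteins 37 rose and 32 fell when adjusted over the list alone, for hnRNPs 74 and 30, and for the CLK list 104 and 38. The named intervals of SRSF9, SRSF10, HNRNPU and HNRNPD hold an annotated exon. A level there can count reads of another exon or isoform, so a fall need not be a fall of an unspliced intron.

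The shares of falls were above those of random gene sets with as many introns, at 23.7% against 2.68%, 14.0% against 3.06% and 13.6% against 3.02% (adjusted permutation p = 0.002 each, with 0.0002 the smallest unadjusted p the sets can give). Against random introns at the same shNC level the expected shares were 7.09%, 5.31% and 5.69% (adjusted permutation p = 0.0013 each), and rises in the CLK list were at 42.5% against 32.5% (0.0068). Against random gene sets the CLK rises did not pass (34.6%, adjusted permutation p = 0.42). Both comparisons were chosen after seeing the data, the second treats introns of 1 gene as independent, and none of these lists passed the Fisher test on genes (adjusted p = 0.163, 0.26 and 0.0871). Neither comparison was matched on annotated exons inside the intron, with which falls were more frequent. The CLK list passed Fisher's exact test without listed value 1, 2 or 3 of shNC (adjusted p = 0.0262, 0.0211 and 0.0236), and the hnRNPs without value 2 (0.0211). By camera with a preset correlation, the gene means of SR proteins were lower than those of other genes (adjusted p = 0.00786, limma), which rises and falls within a gene can give, but with an estimated correlation the adjusted p = 0.425.

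**Figure D4:**
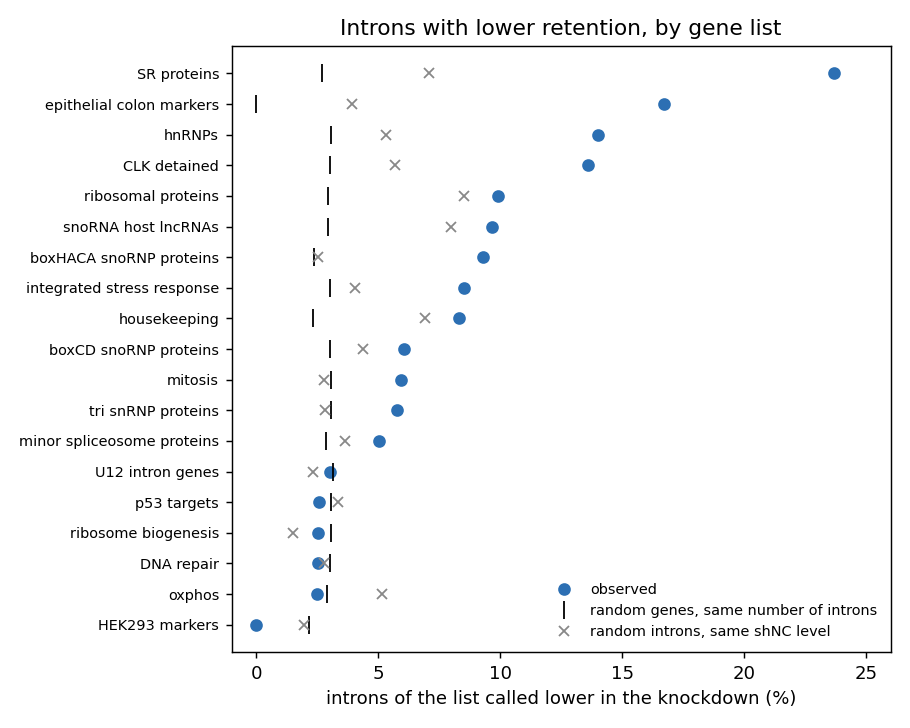
Share of introns called lower in the knockdown (horizontal axis, percent) for each gene list with at least 10 tested introns. Blue points are observed shares, black marks the median of 10000 random gene sets with as many introns, and grey crosses the mean of random introns at the same shNC level; SR proteins lie at 23.7, against 2.68 and 7.09.

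Ribosomal protein genes had 137 introns that rose and 35 that fell of 353 in 78 genes. RPL13A fell from 0.941 ± 0.016 to 0.401 ± 0.025 and 0.452 ± 0.018, and RPLP0 rose from 0.0737 ± 0.0068 to 0.37 ± 0.016 and 0.328 ± 0.031. In 24 non-coding snoRNA host genes 79 rose and 20 fell of 207, with SNHG1 falling at 62853834 to 62854518 from 0.657 ± 0.0081 to 0.159 ± 0.011 and 0.22 ± 0.014. The SNHG1 interval holds an annotated exon, so its fall need not be a fall of an unspliced intron. In 41 genes of ribosome biogenesis 140 rose and 11 fell of 437, led by NOP14 (0.0203 ± 0.0032 to 0.351 ± 0.012 and 0.261 ± 0.001). Adjusted over the list alone, 147 rose and 38 fell, 84 and 22, and 139 and 11.

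Falls in ribosomal protein genes, at 9.92%, and in snoRNA host genes, at 9.66%, were above random gene sets (2.96% and 2.94%, adjusted permutation p = 0.002 and 0.013). They were not separated from random introns at the same shNC level (8.53% and 7.97%, adjusted permutation p = 0.7 each), but rises in ribosomal protein genes, at 38.8%, were above such introns (27.5%, adjusted permutation p = 0.0013) but did not pass against random gene sets (30.6%, adjusted permutation p = 0.082). These comparisons were chosen after seeing the data and were not matched on annotated exons inside the intron. By Fisher's exact test on genes ribosomal proteins, snoRNA hosts and ribosome biogenesis did not pass (adjusted p = 0.163, 0.42 and 0.174). With wider bounds ribosomal proteins and ribosome biogenesis did (Fisher's exact test, adjusted p = 0.00727 each), as on an arcsine scale (0.000362 and 0.00398). Ribosomal proteins also passed Fisher's exact test without listed value 2 of shNC (adjusted p = 0.0427), and snoRNA hosts without value 3 (0.0411). By camera, the gene means of ribosomal protein genes rose less than those of other genes at the preset correlation (limma adjusted p = 0.0406) but not at an estimated correlation (adjusted p = 0.425).

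Of 36 mitotic genes 35 had a called intron, against 74.8% of all genes, with 176 introns that rose and 24 that fell of 404. ESPL1, the separase gene, rose from 0.00533 ± 0.0012 to 0.235 ± 0.019 and 0.203 ± 0.0029, and SMC1A, a cohesin gene, from 0.00467 ± 0.0032 to 0.102 ± 0.0042 and 0.0867 ± 0.0059. Of 45 DNA repair genes 41 had one, with 261 that rose and 17 that fell of 675: ERCC2, the XPD helicase gene, rose from 0.00733 ± 0.00058 to 0.34 ± 0.086 and 0.286 ± 0.036, and LIG1, a DNA ligase gene, from 0.008 ± 0.0017 to 0.251 ± 0.018 and 0.146 ± 0.023. For mitosis 190 rose and 24 fell when adjusted over the list alone, and for DNA repair 272 and 19.

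In the fit reported, mitosis was the only list to pass Fisher's exact test on genes (adjusted p = 0.0145). Its genes have a median of 10 tested introns, and among genes with at least that many the adjusted p was 1.0. The call was also lost among introns without annotated exons (adjusted p = 0.151), among introns with a mean level of at least 0.05 (0.187), and without listed value 1 or 3 of sh15.5K-1 (adjusted p = 0.203 and 0.0991), value 3 of sh15.5K-2 (0.0629) and value 3 of shNC (0.0512). DNA repair did not pass Fisher's exact test (adjusted p = 0.0871), but did with wider bounds (0.0362), a single prior variance (0.0358) and an arcsine scale (0.0363). It also passed Fisher's exact test without listed value 2 or 3 of sh15.5K-1 (adjusted p = 0.024 and 0.0289) and without value 1, 2 or 3 of shNC (0.0262, 0.00663 and 0.000877). Among genes with many introns its adjusted p by Fisher's exact test was 1.0, and by camera at an estimated correlation neither list passed (limma adjusted p = 0.748 and 0.656). Against random introns at the same shNC level, rises were at 43.6% against 32.0% for mitosis and 38.7% against 33.1% for DNA repair (adjusted permutation p = 0.0013 and 0.0057), and falls in mitosis at 5.94% against 2.78% (0.0043). That comparison treats introns of 1 gene as independent. Against random gene sets, which keep genes whole, none of these passed: rises were at 33.8% and 34.5% in the sets (adjusted permutation p = 0.092 and 0.55), and falls in mitosis had 0.092. Both comparisons were chosen after seeing the data and were not matched on annotated exons inside the intron.

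Of 24 p53 targets 18 had a called intron, with 67 introns that rose and 4 that fell of 156, such as FDXR, from 0.0213 ± 0.0078 to 0.456 ± 0.059 and 0.248 ± 0.03. In 50 respiratory chain genes 105 rose and 6 fell of 241, among them NDUFS8, from 0.00767 ± 0.0015 to 0.172 ± 0.012 and 0.101 ± 0.014. In 21 stress response genes 55 rose and 13 fell of 153, and ASNS, the asparagine synthetase gene, fell from 0.726 ± 0.016 to 0.244 ± 0.04 and 0.354 ± 0.031. In 10 housekeeping genes 14 rose and 4 fell of 48, with ENO1 falling and PPIA rising. Adjusted over the list alone, 67 rose and 4 fell for p53 targets, 107 and 8 for the respiratory chain, 56 and 13 for the stress response and 14 and 4 for housekeeping genes. Of these 4 lists only the respiratory chain differed from random gene sets, a comparison chosen after seeing the data, in the share of rises (43.6% against 30.8%, adjusted permutation p = 0.045), and against introns at the same shNC level (31.0%, adjusted permutation p = 0.0013); its Fisher's exact test on genes gave a Benjamini-Hochberg adjusted p of 1.0. By camera the respiratory chain went down relative to other genes and did not pass (limma adjusted p = 0.733 at the preset and 0.764 at an estimated correlation).

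Marker genes show which cells the table reflects only through the introns it lists. Of 19 genes abundant in HEK293 cells 12 had tested introns, among them NEFM, IGF2BP1 and IGF2BP3, with 12 introns that rose and none that fell of 48. Of 20 colonic epithelial genes 4 had tested introns, among them CDX2, KRT8 and KRT18, with 8 that rose and 4 that fell of 24. Of 18 genes of fibroblasts, endothelium and blood 1 had, and neither of its 2 introns was called. Adjusted over the list alone, 11 rose and none fell for HEK293 genes, and 8 and 4 for colonic genes. No expression level is given, so these counts do not measure abundance, and the named introns of KRT8 and KRT18 overlap on opposite strands.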

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

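Chosen only after the result was seen were the tests of regression to the mean and of exons inside falling introns, both tests on SNU13, and the wider limits of the variance test. Between the hairpins, a test of the difference itself called 154 introns higher and 25 lower in sh15.5K-1 than in sh15.5K-2. The named introns had limma adjusted p-values of 0.0429 for SLC2A6, 0.0473 for SSH3, 0.0337 for LMF2, 0.0456 for RAB5IF, 0.0195 for ATP7B and 0.0479 for NSMAF. In SLC2A6 the level was 0.323 with sh15.5K-1, 0.021 with sh15.5K-2 and 0.028 in shNC, whereas in ATP7B the sh15.5K-1 level of 0.671 lay below and the sh15.5K-2 level of 0.956 above the shNC level of 0.774. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05: the real split called 179 introns and the highest other 3. In the authors' deposited table, introns listed for 1 hairpin only, and so in no comparison here, had an adjusted p-value under 0.05 in 544 of 6203 cases for sh15.5K-1 (487 higher, 57 lower) and in 1003 of 7294 for sh15.5K-2 (913 higher, 90 lower).

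The first pattern is the excess of rises over falls. Even intronic background would add the same odds to every intron of a gene if reads were scaled by length and spliced support was even. The variance of the odds change between introns of a gene was 8.06 times that expected from the libraries (median of 149 genes, and 5.69 to 10.2 under other limits). Neither condition can be checked here, so this ratio cannot exclude background as the only cause. Loss of spliced mRNA of a whole gene would multiply the odds of every intron by 1 factor. On the log odds scale, however, the ratio was 3.61 (2.24 to 7.49 under other limits). In these genes a loss by 1 factor per gene can thus not be the only cause, but the test cannot tell whether it contributed. Reads of annotated exons cannot be the whole cause because 31.3% of introns without such exons were called higher. Of the called introns without them 97.2% rose, a share that the lower bound on the level can raise. Chance is argued against for both hairpins together: only the real 1 of 84 splits of the libraries called as many introns, 26394 against at most 646. That 1 of 84 is the smallest share these splits can give. In splits that mix groups, the difference between groups adds to the spread and lowers the calls, so the gap itself adds little. For each hairpin alone 10 splits are too few, with 28783 and 20999 called against 0. Less efficient splicing after knockdown of SNU13 may account for the pattern, as a hypothesis that was not tested, and SNU13 protein was not measured. Depth differences alone are argued against, since depth sets the spread of a level rather than its mean. The mean level of tested introns was 0.1577 ± 0.00042 (SD, n = 3) in shNC, 0.1966 ± 0.0016 in sh15.5K-1 and 0.1868 ± 0.00059 in sh15.5K-2. How far depth shaped the counts of calls stays open because no read counts were used.

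The second pattern is the set of falling introns. If transcripts annotated for nonsense-mediated decay had become more visible, introns found only in them should have fallen more often by an odds ratio above 1.5. Against other introns without a protein-coding transcript it was 1.21 (95% interval 1.01 to 1.45, with 11.1% of 2018 against 8.38% of 3805). The odds ratio stayed under that set limit, but its interval lay above 1, so a smaller part in the falls is left open. Exons inside the interval are a candidate explanation for part of the falls, with an odds ratio of 1.37 (1.2 to 1.56) at the same shNC level. Both 95% intervals treat introns of 1 gene as independent. Regression to the mean cannot be the whole cause: of introns called lower with 1 hairpin against 2 shNC libraries, at least 89.4% had a level in the left-out shNC library above the mean of the other hairpin, in each of the 6 choices. The split of the libraries as labelled called 2423 introns lower, against 632 in the split of sh15.5K-1 from all others, which holds a difference between groups, and at most 40 in splits that mixed groups. In those mixed splits the difference between groups adds to the spread, which lowers the calls.

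The third pattern is the rise of all 3 tested introns of SNU13. The general rise alone is argued against, since the mean log odds change of SNU13, 2.86 and 2.65 for the hairpins, exceeded that of 99.9% of 8256 genes with at least 3 tested introns. Degradation of spliced SNU13 mRNA by the hairpins and less splicing of SNU13 itself cannot be told apart: the smallest change among its introns, 2.47 and 2.38, exceeded that of 99.9% of genes, which both would give. Each of the 3 intervals holds an annotated exon, 2 of them overlap, and no mRNA level was used.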

How the results depend on the processing

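Chosen only after seeing the data were the single prior variance, introns without annotated exons, the arcsine scale, a mean level of at least 0.05, the authors' adjusted p-value, and the matched sets and level bins. No paired analysis was possible because the listed values carry no replicate number. Rises outnumbered falls in both hairpins together and in each alone under every setting run. For both together, for sh15.5K-1 and for sh15.5K-2, a change of at least 0.1 left 8477, 9477 and 6870 higher and 1248, 1220 and 1059 lower, and of at least 0.2 left 3739, 4421 and 3093 higher and 535, 573 and 512 lower. Introns without exons gave 10183, 11162 and 7222 higher and 272, 217 and 197 lower, with fewer introns tested. At an adjusted p under 0.01, sh15.5K-1 and sh15.5K-2 had 17720 and 11694 higher, and falls numbered 1378, 1146 and 966. A mean level of at least 0.05 gave 15648 higher together and 15257 for sh15.5K-1, and 3024 were lower for sh15.5K-2 in the authors' deposited table. Between hairpins, the counts higher and lower were 23 and 8 (change of 0.1), 8 and 4 (0.2), 19 and 7 (wider bounds), 38 lower (single prior), 0 and 0 at an adjusted p under 0.01, without exons, by arcsine and by level, and 0 to 747 and 0 to 56 leaving out 1 library. Without listed values 1, 2 and 3 of sh15.5K-1 these were 582, 487 and 803 in all, and without any shNC value 0. The 8 limma fits with 0 calls had 11.5% to 14.3% of introns at an unadjusted p under 0.05, against 11029 (13.7%) in the fit reported. The median change was 0.0078 (bounds), 0.0077 (arcsine) and 0.0518 (level), 0.0126 to 0.0131 leaving out 1 library. The U12 odds ratio was 0.854 (bounds) and 0.838 (arcsine), past the threshold, 1.22 (level), and 0.881 to 0.96 leaving out 1 library. For box C/D falls it was 1.58 (level) and 1.41 (level bins), both short of the threshold, and 2.63 to 3.87 leaving out 1 library; introns without exons gave no value. Spearman's correlation with length was -0.28, -0.267, -0.141 and -0.085 in the shNC level bins from 0.01 to 0.05, 0.05 to 0.2, 0.5 to 0.8 and 0.8 to 1. Lists called numbered 5 (bounds), 2 (single prior), 0 (without exons), 6 (arcsine), 0 (level), 0 (genes with many introns), 6 (sets matched on intron number), 7 (level-matched introns), 2 (camera at the preset correlation, 0 at an estimated one) and 0 to 5 leaving out 1 library. The cause was not tested. Of 118 named introns, at most 5 lost their call in any setting and none changed sign. Only 35 had a value without exons and 109 by level. These counts do not cover the calls between hairpins, which were lost in the settings with 0 calls. A coverage minimum, low-coverage marks, DESeq2, a replicate block, GC content and a sequence definition of U12-type introns were not run, and depth sets an unknown limit on each level.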

Other observations

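Ranked by the mean log odds change over genes with at least 3 tested introns, a ranking chosen only after the data were seen, MROH1 came first (4.75 over 4 introns), followed by RRAS (4.14 over 5 introns) and MRPL20-AS1 (3.31 over 3 introns). ICAM5, an adhesion molecule gene, had 2.98 over 4 introns and ADCY7, an adenylyl cyclase gene, 2.77 over 4 introns. SNU13 ranked 7 with 2.75 over 3 introns. WDR90 and IFRD2 had 2.75 over 11 introns and 2.68 over 14 introns.

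Introns listed only in transcripts annotated for nonsense-mediated decay had a median shNC level of 0.941, against 0.0113 for introns of at least 1 protein-coding transcript. Of the former 16.7% rose and 11.1% fell, and of the latter 33.6% rose and 2.61% fell. At equal shNC level the 95% interval of the Mantel-Haenszel odds ratio held 1 for falls (0.859 to 1.18) and for rises (0.869 to 1.15). Introns with shNC levels above 0.8 rose in 9.54% and fell in 10.7% of 8666 cases.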
